A study of Homo sapiens with 30 samples.

How the data were processed

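Single-cell RNA sequencing was performed on scalp biopsies of patients with alopecia areata, an autoimmune disease in which hair follicles are attacked and hair is lost, and of matched healthy controls. Per the labels, 13 patients gave lesional or nonlesional skin and 11 controls gave healthy skin. The 30 libraries comprised 11 healthy control, 7 nonlesional and 12 lesional libraries, named here by group and replicate, with replicates 1 to 11 in controls, 12 to 18 in nonlesional skin and 19 to 30 in lesional skin. Per the labels' protocols, cryopreserved tissue was thawed, digested with Liberase TL (a collagenase blend) and loaded for 10x Genomics 5' version 2 libraries. All libraries carried the same batch label, 1.

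The deposited values were raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization. Counting was done with Cell Ranger 8.0.0, per the file headers, against genome build GRCh38, per the submitters' processing notes. The settings of the read counting, including its use of strand, were not given in the sources used here, so antisense genes are reported as uncertain, as are HLA genes that share sequence with near-identical relatives. The same 38606 genes were listed for all libraries. Control replicates 1 to 6 were deposited with all barcodes (318441 to 444185 per library) and the other 24 libraries with 168 to 8779 barcodes that each held at least 500 UMIs. The 6 libraries with all barcodes were all controls.

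In every library, cells were kept with at least 500 UMIs, at least 300 detected genes and at most 20% mitochondrial UMIs, which gave 51943 cells. Scrublet (run through scanpy 1.11.5) marked 92 of them (0.177%) as doublets. A caller that marks so few cells has not worked, so doublets are to be taken as still present, although the 92 were removed. As an added alternative, the cells with the highest doublet scores, 1305 in all (2.51%), were removed. The 51851 kept cells were spread over libraries at 160 to 8251 each. Median UMIs per kept cell ranged from 716 to 7802 between libraries, and the median mitochondrial share from 2.55% to 14.1%. None of median UMIs, median genes, median mitochondrial share or kept cells differed between groups (permutation tests over 12 comparisons, exact where nonlesional libraries entered, adjusted p from 0.921 to 0.95).

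Counts per cell were scaled to 10000, log-transformed, reduced to 2000 variable genes and 30 principal components, and clustered without integration on 15 neighbours with the Leiden algorithm at resolution 1 (igraph 0.11.9). Of 64 clusters, 54 were named from fixed markers, as "X-like" classes, and 10 clusters with 7012 cells stayed unnamed. A name required at least 3 raised markers. The requirement of at least 5 markers where none led the cluster was set after the clusters were seen, and it kept clusters 28, 42 and 54 unnamed. Cluster 28 made up 2.07% of control, 1.86% of nonlesional and 4.74% of lesional cells on average. Cluster 42 made up 0.0461%, 0.0110% and 0.696%, with 80.1% of its cells in lesional replicate 29. Cluster 54 made up 0.0386% of control cells, all in control replicate 11, and was absent from the other groups. The 1238 T and NK-like cells were clustered again into 11 subclusters on 1000 variable genes and 15 components. This gave 143 CD4 T-like, 165 CD8 T-like and 134 regulatory T-like cells, with 796 cells unnamed. Cell names were rebuilt from markers and may differ from the authors' names.

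The library was the replicate in every test, never the cell. Shares of cells were compared as the difference in mean percent per library with a two-sided permutation test (100000 resamples, or exact where a group held fewer than 10 libraries), adjusted by Benjamini-Hochberg over the 12 classes or 3 subclasses. Raw counts were summed per library and class, and the sums were tested with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM scaling, filterByExpr, R 4.3.3), with all 3 groups in 1 fit and an adjusted p threshold of 0.05. This version of edgeR stops without a dispersion estimate, so estimateDisp was run first, a step added before any count of genes was seen. A library entered with at least 20 cells of a class, or 100 for all cells together. A comparison was run with at least 4 such libraries per group. Controls, lesional and nonlesional libraries with enough cells numbered 11, 12 and 7 for all cells, keratinocyte-like and vascular endothelial-like cells, 8, 10 and 5 for fibroblast-like cells. They numbered 6, 9 and 2 for T and NK-like cells, and 1, 4 and 0 for myeloid-like cells. T and NK-like cells could therefore be tested between lesional and control skin alone, and myeloid-like cells in no comparison. While run time was measured, mural-like cells, sweat gland-like cells and the sum of named cells were also fitted once; those fits are not reported. Sex-linked genes that reveal donor sex and variable segments of immune receptors, 698 in all, were left out. Levels are given as CPM, the summed counts scaled by library size, as mean ± SD over libraries. Changes are given as log2 fold changes with standard errors (SE).

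The 27 gene lists were fixed before the data were examined, as were the cell markers, the designs and most alternatives. Lists with at least 5 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, and again with an estimated correlation, and p was adjusted over the lists of a class and comparison. Camera compares a list with the other genes of the same class. Genes were named by a fixed rule with 3 parts. Per class and comparison, it took up to 5 genes per direction with the smallest p among those past the threshold with an absolute log2 fold change of at least 1, leaving out clone-named and LINC genes. It added up to 4 members per described list past the threshold, and 30 fixed genes of immunity, antigen presentation and hair. Of these 30 genes, 26 were tested and 22 of them in a named class; IL13, CCL13, CCL18 and CXCL11 were too low to test. A gene that the rule takes is not reported here. Gene positions were taken from GENCODE release 29 on GRCh38 by gene identifier.

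Total UMIs per library ranged from 805668 to 38986695, and in the controls with all barcodes 30.1% to 74.9% of UMIs lay in kept cells. The test was tried on simulated counts with 200 genes changed by known folds. For lesional against control keratinocyte-like cells (13147 genes), 77% of the 2-fold and 92% of the 4-fold changes were recovered, with 8 false calls. The shares recovered were 59% and 93% for all cells (18139 genes), 42% and 82% for fibroblast-like cells (6054 genes), 89% and 97% for vascular endothelial-like cells (11543 genes), and 48% and 89% for T and NK-like cells (3043 genes) in the same comparison.

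Nonlesional and lesional libraries could be matched into 6 pairs by a number in the deposited names, which the labels do not explain. Paired keratinocyte-like sums deviated together from their group means in 6 of 6 pairs (r from 0.114 to 0.648, median 0.366, against a median of -0.0412 for other combinations), and each matched best with its own partner. For vascular endothelial-like cells 5 of 6 pairs had r over 0.1 (0.0778 to 0.714), and for all cells 3 of 6 (-0.201 to 0.832). Patients who gave both kinds of skin were otherwise treated as independent samples. No pair of libraries looked like a duplicate: the lowest chi-square per gene between libraries of a group ranged from 6.21 to 24.6. Alternatives tried were a minimum of 1000 UMIs, at most 10% mitochondrial UMIs, no doublet removal, Leiden resolution 2 (88 clusters) and no low-count filter. Further ones were DESeq2 1.42.0, edgeR on cell counts, an estimated correlation and the pairs as a block. A stricter cell call in the controls with all barcodes, and leaving those controls out, were also tried. Leiden resolution 2 and the stricter call in those controls were applied to shares of cells alone, and no gene was tested with them. Keeping only those controls, removing the highest doublet scores, taking shares of named cells and leaving out each library in turn for keratinocyte-like cells, T and NK-like cells and shares were added after seeing the data.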

Results

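The dataset comprised 30 single-cell libraries of human scalp: 11 from healthy controls, 7 from nonlesional and 12 from lesional skin of patients with alopecia areata. Total UMIs per library ranged from 805668 to 38986695, and 160 to 8251 cells per library were kept, 51851 in all. Clusters were named from fixed markers as X-like classes. The most numerous were keratinocyte-like (16918 cells), vascular endothelial-like (11972) and sweat gland-like cells (5631), followed by mural-like (3338), fibroblast-like (2271), T and NK-like (1238) and sebocyte-like cells (1021). Smaller classes were hair shaft and inner root sheath-like (693 cells), melanocyte-like (585), myeloid-like (553), lymphatic endothelial-like (314) and Schwann-like cells (305). The design set patients against controls, in lesional and in nonlesional skin, and both kinds of patient skin against each other.

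Lesional scalp was compared with healthy scalp to find which cells and genes differ where hair was lost. In keratinocyte-like cells of lesional skin the list of genes that present antigen on MHC class I, the molecules through which CD8 T cells recognise their targets, was raised with 6 of 12 genes past the threshold. In the same cells the lists of the follicle's outer root sheath and stem cells (3 of 16 genes), keratinocyte activation (2 of 12) and the extracellular matrix (3 of 14) were lowered. None of these list calls held with an estimated correlation (adjusted p = 0.074, 0.257, 0.074 and 0.183 in this order). In T and NK-like cells IL17A, the cytokine that defines type 17 T cells, fell, a call lost without control replicate 11 or lesional replicate 30 (adjusted p = 0.0524 and 0.0542). The chemokine and interferon-gamma response lists rose there. No cell class differed in its share of cells after adjustment.

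Among keratinocyte-like cells, 290 of 13147 genes changed between lesional and control skin (edgeR, adjusted p under the threshold of 0.05), of which 84 rose and 206 fell. Among those that rose and met the naming rule, HLA-F had the smallest p (ENSG00000204642, chromosome 6, 29722775 to 29738528, GRCh38). This MHC class I molecule stood at 75.8 ± 32.2 CPM in lesional (n = 12) and 31.2 ± 12.6 in control libraries (n = 11). Its log2 fold change was 1.18 (SE 0.225, adjusted p = 0.00602), and 12 of 12 lesional libraries lay above the control median. Of 12 measured genes of the MHC class I list, 6 rose, 0 fell and 6 did not pass, and 8 rose when p was adjusted over the list alone. HLA-C, another class I molecule, stood at 625 ± 268 against 314 ± 120 CPM (log2 fold change 0.99, SE 0.240, adjusted p = 0.0248, 11 of 12 libraries above the control median). PSMB9, a subunit of the immunoproteasome that cuts peptides for presentation, stood at 87.8 ± 26.6 against 40.6 ± 20.9 CPM (0.98, SE 0.228, adjusted p = 0.019, 12 of 12). TAP1, which carries those peptides into the endoplasmic reticulum, reached 49.3 ± 10.6 against 31.0 ± 9.33 CPM (0.61, SE 0.150, adjusted p = 0.0283, 12 of 12). The list was raised as a set (camera adjusted p = 7.31e-11; median log2 fold change 0.69), with adjusted p = 0.074 with an estimated correlation. Reads of HLA genes can be shared with related HLA genes, so the split between HLA-F and HLA-C is uncertain.

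The interferon-gamma response list was also raised in lesional keratinocyte-like cells: 3 of 13 genes rose, 0 fell and 10 did not pass, with 4 that rose when adjusted over the list alone. The camera adjusted p was 0.00171, or adjusted p = 0.318 with an estimated correlation. PSMB9 and TAP1, described above, were among those that rose. The type I interferon list was raised with 0 of 13 genes past the threshold by edgeR (1 when adjusted over the list alone). Its camera adjusted p was 0.00359, or 0.341 with an estimated correlation. Without the controls deposited with all barcodes this call was lost (camera adjusted p = 0.0914). Other genes that rose and met the naming rule were ZMAT1, a zinc finger protein (log2 fold change 1.24, adjusted p = 0.0115), and CACNB2, a calcium channel subunit (2.00, adjusted p = 0.0132). They also included RAB26, a small GTPase of vesicle traffic (1.63, adjusted p = 0.0136), and the antisense transcript SLC38A4-AS1 (1.18, adjusted p = 0.00701), which is uncertain because the use of strand in the counting was not given. Between 11 and 12 of the 12 lesional libraries lay above the control median for each.

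**Figure D1:**
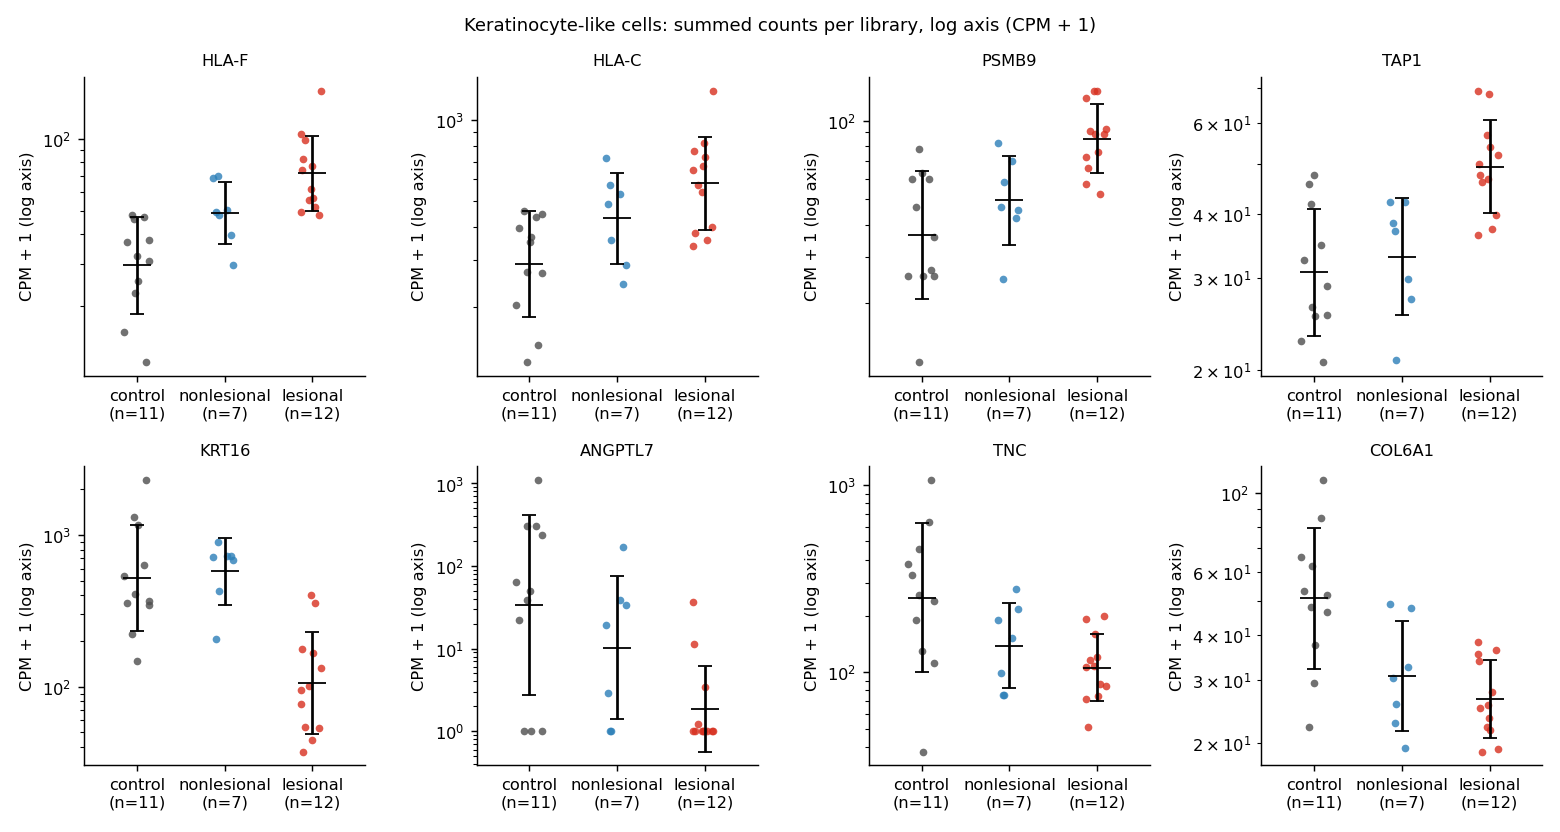
CPM (+1, log axis) of 8 genes in keratinocyte-like cells by group; each point is a library and bars show the mean ± SD of log10(CPM + 1). HLA-F lay above the control median in 12 of 12 lesional libraries and KRT16 in 0 of 12.

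Genes of the outer root sheath and follicle stem cells fell in lesional keratinocyte-like cells. Of 16 measured genes 3 fell, 0 rose and 13 did not pass, and 6 fell when adjusted over the list alone; the camera adjusted p was 3.69e-05, with adjusted p = 0.257 with an estimated correlation. ANGPTL7 (ENSG00000171819, chromosome 1, 11189341 to 11195981), a secreted angiopoietin-like protein, stood at 4.05 ± 10.3 CPM in lesional and 192 ± 324 in control libraries (log2 fold change -5.43, SE 1.07, adjusted p = 0.00701, 12 of 12 below the control median). LGR5, a receptor of follicle stem cells for R-spondins, which strengthen Wnt signalling, stood at 22.2 ± 25.5 against 138 ± 182 CPM (-2.57, SE 0.703, adjusted p = 0.0459, 11 of 12 below). CD34, a marker of stem and endothelial cells, changed by -2.95 (SE 0.768, adjusted p = 0.0345, 12 of 12 below). Of 12 genes of follicle matrix and hair growth signalling, 2 fell, 0 rose and 10 did not pass, with 2 that fell adjusted over the list alone, but the list did not move as a set (camera adjusted p = 0.909). They were FGF18, a growth factor of the resting follicle (-3.85, SE 0.781, adjusted p = 0.00892, 11 of 12 below), and HOXC13, a transcription factor for hair keratin genes (-1.82, SE 0.489, adjusted p = 0.0411, 9 of 12 below).

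The keratinocyte activation list, made of stress keratins and S100 proteins, fell as well. Of its members, 2 of 12 genes fell, 0 rose and 10 did not pass, with 3 that fell when adjusted over the list alone (camera adjusted p = 5.31e-08; adjusted p = 0.074 with an estimated correlation). KRT16 (ENSG00000186832, chromosome 17, 41609778 to 41615899), a keratin of activated epidermis and of the outer root sheath, stood at 140 ± 120 CPM in lesional and 709 ± 645 in control libraries. Its log2 fold change was -2.32 (SE 0.437, adjusted p = 0.00602, 12 of 12 below the control median). KRT6C, a keratin of the same kind with close paralogs, changed by -2.65 (SE 0.648, adjusted p = 0.0264, 11 of 12 below). Of the extracellular matrix list, 3 of 14 genes fell, 0 rose and 11 did not pass; adjusted over the list alone, 9 fell and 1 rose (camera adjusted p = 2.25e-06; adjusted p = 0.183 with an estimated correlation). COL6A1, a chain of collagen VI, stood at 26.4 ± 6.92 against 54.5 ± 24.7 CPM (-1.05, SE 0.214, adjusted p = 0.00944). Tenascin C (TNC), a matrix glycoprotein, stood at 113 ± 47.5 against 347 ± 292 CPM (-1.64, SE 0.342, adjusted p = 0.0105). Both lay below the control median in 12 of 12 libraries. COL6A2 changed by -1.28 (SE 0.284, adjusted p = 0.0143, 12 of 12 below). Clusters 48 and 49 of this class each also raised 3 fibroblast markers. Cluster 48 held 180 cells, all of 1 control library, and cluster 49 held 121 control, 127 nonlesional and 0 lesional cells. Whether fibroblast RNA or mixed cells gave part of the fall in matrix genes was not tested.

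The 5 genes with the smallest p among those that fell and met the naming rule all had adjusted p = 0.00406. They were CDC42EP3, an effector of the GTPase CDC42 (log2 fold change -2.33), IGFBP2, which binds insulin-like growth factors (-1.82), and the tubulin TUBB2B (-3.19). The others were the scavenger receptor protein SSC5D (-3.51) and the secreted protease PRSS23 (-2.15). Each lay below the control median in 11 or 12 of 12 libraries. Signs of tissue handling moved with these groups. The dissociation and early response list was raised in lesional keratinocyte-like cells (0 of 20 genes past the threshold and 0 adjusted over the list alone, 19 higher; camera adjusted p = 2.25e-06; adjusted p = 0.341 with an estimated correlation). Of 12 mitochondrially encoded genes, 1 rose, MT-ND2, a subunit of complex I (log2 fold change 0.87, SE 0.211, adjusted p = 0.0242), and 2 rose adjusted over the list alone (camera adjusted p = 4.89e-06; adjusted p = 0.331 with an estimated correlation). The clusters within the class also differed in weight. Cluster 3, led by CBLN2, KRT16 and KRT6C, made up 10.5 ± 7.49% of control and 1.34 ± 2.37% of lesional keratinocyte-like cells. Cluster 27, led by WIF1 and DIO2 among others, made up 21.8 ± 18.9% and 8.58 ± 8.52%. Cluster 11, led by VNN1 and GPX2, made up 25.0 ± 13.6% and 31.9 ± 25.5%. Cluster 41, which ANGPTL7 and TNC lead, drew 92.1% of its cells from control replicate 11.

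The count of 290 genes by edgeR, against 568 by DESeq2, depended on which controls entered. It was 609 without the 6 controls deposited with all barcodes, 0 with those 6 as the only controls, and between 133 and 383 when a single library was left out. It fell below 290 by more than 1.5 times without control replicates 7 (133), 8 (192), 10 (148) and 11 (167) and without lesional replicates 21 (187), 25 (144) and 26 (182).

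Lesional T and NK-like cells were compared with those of controls in 9 and 6 libraries. Their unnamed subcluster 8 (101 cells) had the keratin KRT14 detected in 68.3% and CD3E in 35.6%. Subcluster 10 (14 cells) had the endothelial gene PECAM1 in 85.7%. Both stayed in the sums, and whether RNA of other cells gave part of the changes below was not tested. Of 3043 genes 3 fell and 0 rose (edgeR; 210 at an unadjusted p under 0.05, and 2 calls with DESeq2). IL17A (ENSG00000112115, chromosome 6, 52186375 to 52190638), the signature cytokine of type 17 T cells, stood at 12.0 ± 23.9 CPM in lesional and 331 ± 419 in control libraries. Its log2 fold change was -4.02 (SE 0.716, edgeR adjusted p = 0.0144), and 9 of 9 lesional libraries lay below the control median. Control replicate 11 alone stood at 1.15e+03 CPM; without it the control mean was 168 CPM and the log2 fold change -3.19 (adjusted p = 0.0524), and without lesional replicate 30 it was -3.87 (adjusted p = 0.0542). FKBP11, a protein-folding enzyme of the secretory pathway, stood at 110 ± 39.4 against 269 ± 197 CPM (-1.47, SE 0.296, edgeR adjusted p = 0.0334, 9 of 9 below), and without control replicate 10 the control mean was 190 CPM and the log2 fold change -0.838 (adjusted p = 0.44). FKBP11 was also lost without control replicate 11 and lesional replicates 19, 25 and 30 (adjusted p from 0.0524 to 0.104). The long noncoding RNA LINC01871 (-1.47, SE 0.300, adjusted p = 0.0334) fell outside the naming rule and was chosen after its values were seen. It was lost without control replicates 5, 7, 8 and 11 and lesional replicates 19, 25, 28 and 30 (adjusted p from 0.0524 to 0.077). Of 5 type 17 genes 1 fell, 0 rose and 4 did not pass, with 2 that fell adjusted over the list alone (camera adjusted p = 2.65e-08; adjusted p = 0.00689 with an estimated correlation). The number of genes was 97 without the low-count filter and 0 at a minimum of 1000 UMIs per cell. It was 6 and 0 without control replicates 5 and 11, and 1, 5, 7, 9, 1, 5 and 0 without lesional replicates 19, 20, 22, 23, 25, 29 and 30.

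The chemokine and receptor list rose in lesional T and NK-like cells, with all 7 measured genes higher, 0 past the threshold over all genes and 2 adjusted over the list alone. The set passed (camera adjusted p = 0.00037, median log2 fold change 1.46; adjusted p = 0.0393 with an estimated correlation). CXCR3, the receptor for interferon-induced chemokines, stood at 165 ± 64.9 against 50.2 ± 30.2 CPM (1.53, SE 0.340, edgeR adjusted p = 0.0646, 9 of 9 libraries above the control median). The chemokine CCL5 stood at 847 ± 455 against 329 ± 202 CPM (1.46, SE 0.401, edgeR adjusted p = 0.155, 8 of 9). Neither passed over all genes. The interferon-gamma response list rose with 7 of 8 genes higher, 0 past the threshold over all genes and 2 adjusted over the list alone (camera adjusted p = 0.00894; adjusted p = 0.0393 with an estimated correlation). Of the cytotoxicity list, 0 of 12 genes passed and 2 did adjusted over the list alone (camera adjusted p = 0.0372; adjusted p = 0.383 with an estimated correlation). Its member with the smallest p, the granzyme GZMK, stood at 265 ± 279 against 71.7 ± 74.4 CPM (2.44, SE 0.598, edgeR adjusted p = 0.0927, 8 of 9 above). The control mean was 41.8 CPM without control replicate 7, and GZMK passed without lesional replicate 23 (adjusted p = 0.0421). Other fixed genes of this class did not pass either: IFNG had a log2 fold change of 1.03 (edgeR adjusted p = 0.789), GZMB -0.06 (0.998), PRF1 -0.24 (0.998), CD8A 0.55 (0.88), FOXP3 1.38 (0.895) and CXCL13 3.56 (0.473). The lesional mean of CXCL13 was 168 CPM, or 51.4 without lesional replicate 29. The MHC class II list rose with 6 of 6 genes higher, 0 past the threshold over all genes and 5 adjusted over the list alone (camera adjusted p = 0.000383; adjusted p = 0.154 with an estimated correlation). Signs of tissue handling and RNA quality moved with these lists. The heat shock list rose with 9 of 13 genes higher (camera adjusted p = 0.0186; adjusted p = 0.326 with an estimated correlation). The mitochondrially encoded list rose with 11 of 12 higher (camera adjusted p = 0.000916; adjusted p = 0.326 with an estimated correlation), and in both 0 genes passed over all genes or adjusted over the list alone.

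Within T and NK-like cells, CD8 T-like cells made up 20.3 ± 10.2% in lesional (n = 9) and 8.79 ± 6.16% in control libraries (n = 6; exact permutation p = 0.0308, adjusted p = 0.0839), which did not pass. Regulatory T-like cells made up 13.2 ± 5.96% and 7.47 ± 3.45% (exact permutation p = 0.0559, adjusted p = 0.0839), and CD4 T-like cells 9.44 ± 4.93% and 12.7 ± 8.18% (exact permutation p = 0.356). The CD8 T-like difference passed with edgeR on cell counts (adjusted p = 0.00747) and at a minimum of 1000 UMIs. Of the CD8 T-like cells, CD3E was detected in 83.6% and CD8A in 53.3%. GNLY, XCL2 and NKG7, which NK cells also express, were among their 10 leading genes, so NK cells were not separated from them. Among the unnamed cells, a subcluster of 77 cells from 20 libraries was led by IL17A, IL17F and CCL20. Its share was not compared between groups. Sums over T and NK-like cells follow the mix of their subclusters as well as levels within them. Whether the fall of IL17A or the rise of the chemokine list came from that mix was not tested.

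**Figure D2:**
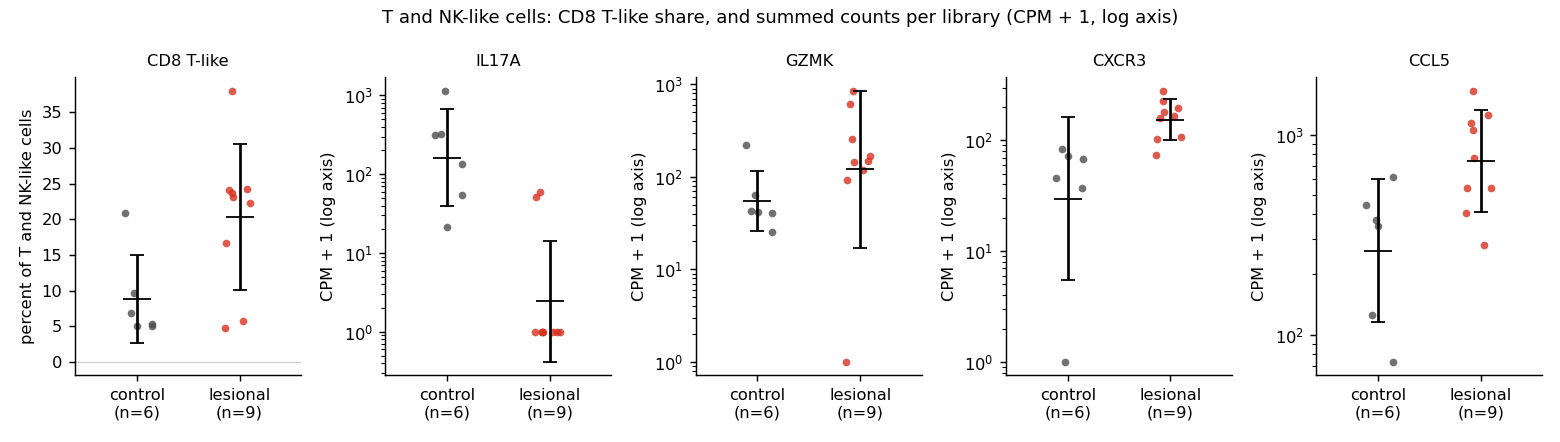
Share of CD8 T-like cells (% of T and NK-like cells) and CPM (+1, log axis) of 4 genes in T and NK-like cells, in control and lesional libraries; each point is a library and bars show the mean ± SD, of log10(CPM + 1) on the log axes. CXCR3 lay above the control median in 9 of 9 lesional libraries and IL17A in 0 of 9.

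Hair shaft and inner root sheath-like cells, which build the hair fibre and its mould, made up 0.116 ± 0.201% of cells in lesional and 2.40 ± 4.39% in control libraries (permutation p = 0.0435, adjusted p = 0.228). This did not pass. Control replicate 4 alone held 14.47%, and without it the control mean was 1.189% and the difference (lesional minus control) -1.074 points in place of -2.281. With edgeR on cell counts this difference passed (adjusted p = 0.0213). The hair shaft keratin KRT85 stood at 5.98 ± 17.7 CPM of all cells in lesional and 304 ± 694 in control libraries (log2 fold change -5.48, SE 1.67, adjusted p = 0.186), and KRT35 differed by -5.47 (SE 1.88, adjusted p = 0.23). T and NK-like cells made up 4.56 ± 4.97% and 2.76 ± 2.42% (permutation p = 0.322, adjusted p = 0.552; a difference of 1.798 points, or 0.5135 without lesional replicate 25).

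Summed over all cells, 0 of 18139 genes changed between lesional and control skin by edgeR, with 2146 at an unadjusted p under 0.05 and 161 by DESeq2. Without the controls deposited with all barcodes, edgeR gave 241 genes (52 up, 189 down), so this 0 depended on those controls. Fibroblast-like cells gave 0 of 6054 by edgeR (424 at an unadjusted p under 0.05, 3 by DESeq2) and vascular endothelial-like cells 0 of 11543 (505 and 0). Gene lists were raised or lowered in 14 of 25 tests for all cells (5 up, 9 down), and 8 of 20 for keratinocyte-like cells (5 up, 3 down). They were moved in 0 of 11 tests for fibroblast-like, 5 of 17 for vascular endothelial-like (2 up, 3 down) and 9 of 11 for T and NK-like cells (8 up, 1 down). Of these 36, the 3 given above for T and NK-like cells held with an estimated correlation, and 23 passed in the same direction without the controls deposited with all barcodes. In vascular endothelial-like cells the type I interferon list was raised (0 of 20 genes past the threshold, 19 higher, camera adjusted p = 3.36e-05; adjusted p = 0.496 with an estimated correlation). In the same cells MHC class II was lowered (0 of 11 past the threshold, 11 lower, camera adjusted p = 0.000218; adjusted p = 0.481 with an estimated correlation). The mitochondrially encoded list, a sign of RNA quality, was raised beside them (0 of 12 past the threshold, 12 higher, camera adjusted p = 0.00194; adjusted p = 0.757 with an estimated correlation). In each case 0 genes passed adjusted over the list alone. Of the 5 lists in these cells, 4 passed in the same direction without the controls deposited with all barcodes. Those controls differed from the other controls in 405 of 11922 genes of these cells (edgeR).

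Nonlesional scalp of patients was compared with healthy scalp to find what differs where hair was kept. Lymphatic endothelial-like cells made up a smaller share of nonlesional skin, at 0.289 ± 0.306% of cells (n = 7) against 0.941 ± 0.424% in controls (n = 11; exact permutation p = 0.00289, adjusted p = 0.0347). Keratinocyte-like cells had 0 changed genes of 13147 by edgeR, with 682 at an unadjusted p under 0.05 and 0 by DESeq2. As a set, their mitochondrially encoded genes were raised (12 of 12 higher, 6 that rose adjusted over the list alone, camera adjusted p = 5.55e-09; adjusted p = 0.605 with an estimated correlation).

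Of 7 nonlesional libraries, 6 lay at or below 0.381% for lymphatic endothelial-like cells. The call was lost at a minimum of 1000 UMIs, at Leiden resolution 2, with edgeR on cell counts, and both without the controls deposited with all barcodes and with those controls alone. When each of the 18 libraries was left out in turn, it held in 4 cases (without control replicates 2, 6 and 10 and nonlesional replicate 14) and was lost in 14, with adjusted p from 0.0074 to 0.0853. Sweat gland-like cells made up 16.9 ± 18.6% in nonlesional and 3.43 ± 4.58% in control libraries (exact permutation p = 0.0247, adjusted p = 0.148), which did not pass; the difference was 13.48 points, or 7.436 without nonlesional replicate 12.

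In nonlesional keratinocyte-like cells the MHC class I list was raised with 0 of 12 genes past the threshold, 0 adjusted over the list alone and 11 higher (camera adjusted p = 0.002; adjusted p = 0.605 with an estimated correlation). The type I interferon list was raised with 0 of 13 genes past the threshold, 0 adjusted over the list alone and 12 higher (camera adjusted p = 0.002; adjusted p = 0.605 with an estimated correlation). KRT16 stood at 628 ± 233 CPM in nonlesional and 709 ± 645 in control libraries (log2 fold change -0.16, SE 0.487, adjusted p = 1). Cluster 18, led by KRT77 and S100P, made up 21.2 ± 30.2% of nonlesional and 2.63 ± 2.13% of control keratinocyte-like cells. It raised 6 keratinocyte markers, 0 of them among its 10 leading genes, and 1 sweat gland marker, so its place in the class is uncertain. A single library gave 27.4% of its cells. Clusters 11 and 27 likewise raised 6 keratinocyte markers each, with 0 among the leading genes. Cluster 27 also raised 1 melanocyte and 1 mural marker, and cluster 11 raised no marker of another class. By this measure the place of clusters 11 and 27 in the class is not certain either. By edgeR, 0 genes passed in all cells (1008 at an unadjusted p under 0.05, 0 by DESeq2), 0 in fibroblast-like cells (232 and 0) and 0 in vascular endothelial-like cells (341 and 0). In the last class HLA-DRA, an MHC class II chain, stood at 1630 ± 228 against 2157 ± 632 CPM (-0.40, SE 0.166, adjusted p = 1). The MHC class II list was lowered with 0 of 11 genes past the threshold, 0 adjusted over the list alone and 11 lower (camera adjusted p = 1.47e-05; adjusted p = 0.516 with an estimated correlation). The mitochondrially encoded list, a sign of RNA quality, was raised beside it with 12 of 12 genes higher, 0 past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.00937; adjusted p = 0.886 with an estimated correlation). Of the 2 lists that passed in vascular endothelial-like cells, 1 passed in the same direction without the controls deposited with all barcodes. Those controls differed from the other controls in 405 of 11922 genes of these cells (edgeR). In all, 17 lists passed over the classes, 0 of them with an estimated correlation and 9 of them in the same direction without the controls deposited with all barcodes.

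Lesional was compared with nonlesional skin of patients to find what differs between affected and spared scalp. T and NK-like cells made up 4.56 ± 4.97% of cells in lesional (n = 12) and 1.13 ± 0.940% in nonlesional libraries (n = 7; exact permutation p = 0.0137, adjusted p = 0.139). Myeloid-like cells made up 1.56 ± 1.91% and 0.298 ± 0.252% (exact permutation p = 0.0232, adjusted p = 0.139). Neither passed after adjustment. Without lesional replicate 25 the differences were 2.144 and 0.8232 points in place of 3.428 and 1.26. Over all cells the cytotoxicity list, made of genes that T and NK cells use to kill, was raised in lesional skin with 10 of 10 genes higher and 0 past the threshold, a call lost with an estimated correlation (adjusted p = 0.0582). KRT16 stood at 140 ± 120 CPM in lesional and 628 ± 233 in nonlesional keratinocyte-like cells (log2 fold change -2.16, SE 0.468, adjusted p = 0.103, 12 of 12 lesional libraries below the nonlesional median), which did not pass. The clusters of the class differed in weight here too. Cluster 3, which KRT16 helps lead, made up 1.34 ± 2.37% of lesional and 8.32 ± 8.29% of nonlesional keratinocyte-like cells. Cluster 18, whose place in the class is uncertain, made up 6.27 ± 8.99% and 21.2 ± 30.2%.

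**Figure D3:**
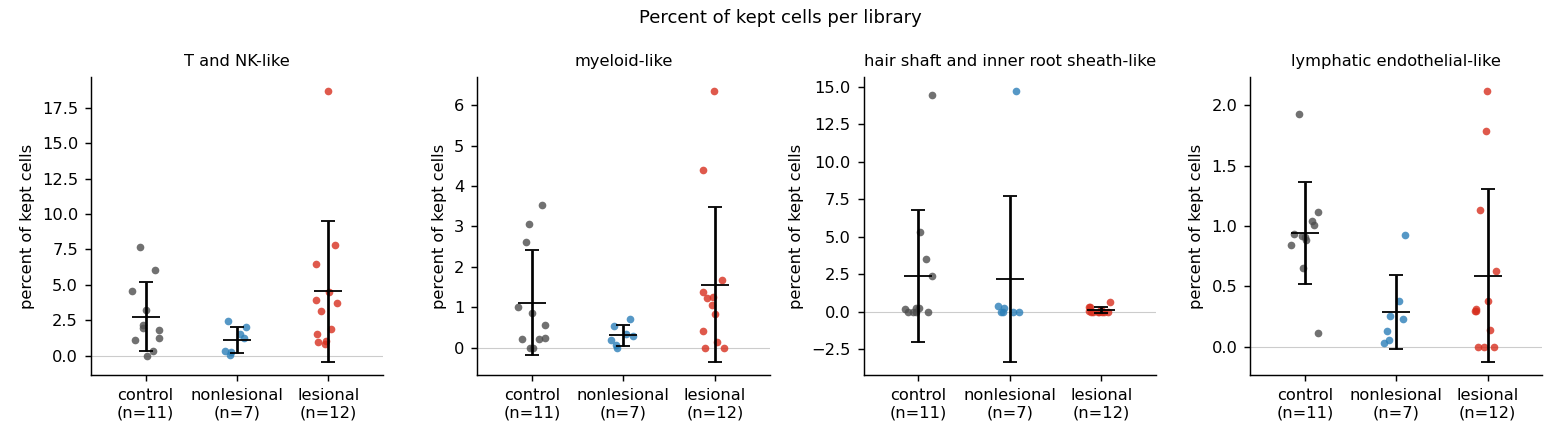
Share of kept cells (%) per library for T and NK-like, myeloid-like, hair shaft and inner root sheath-like and lymphatic endothelial-like cells in the 3 groups; each point is a library and bars show the mean ± SD. T and NK-like cells averaged 4.56% in lesional and 1.13% in nonlesional skin, and lymphatic endothelial-like cells 0.289% in nonlesional and 0.941% in control skin.

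Of the 10 cytotoxicity genes, 0 passed over all genes and 8 rose adjusted over the list alone (camera adjusted p = 1.07e-12; adjusted p = 0.0582 with an estimated correlation). The log2 fold changes over all cells were 3.97 for GZMK (SE 0.903, adjusted p = 0.495) and 2.77 for the chemokine CCL5 (SE 0.715, adjusted p = 0.495, 12 of 12 libraries above the nonlesional median). They were 2.92 for IFNG (SE 0.909, adjusted p = 0.618), which was at 0 CPM in all nonlesional libraries but replicate 14, and 2.62 for CXCR3 (SE 0.744, adjusted p = 0.509). Of 15 inhibitory and activation receptors of T cells, 0 passed over all genes and 8 rose adjusted over the list alone (camera adjusted p = 5.08e-09; adjusted p = 0.0582 with an estimated correlation). With the pairs as a block this call was lost (camera adjusted p = 0.471), and too few cytotoxicity genes were measured to test their list. These sums follow the share of T and NK-like cells as well as levels within them.

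In keratinocyte-like cells 0 of 13147 genes passed by edgeR, with 1014 at an unadjusted p under 0.05 and 13 by DESeq2. With the 6 pairs of libraries as a block, 4 genes rose. They were the protocadherin PCDH7 (log2 fold change 1.18), KITLG, the ligand of the receptor KIT (1.38), the prolactin receptor PRLR (1.51) and the protease inhibitor SERPINB2 (1.62), each at edgeR adjusted p = 0.0426. They were chosen after their values were seen. Nonlesional SERPINB2 averaged 50.5 CPM, or 27.7 without replicate 16. The MHC class I list was raised with 12 of 12 genes higher, 0 past the threshold and 2 adjusted over the list alone (camera adjusted p = 3.15e-05; adjusted p = 0.331 with an estimated correlation). The proliferation list was lowered with 19 of 20 genes lower, 0 past the threshold and 0 adjusted over the list alone (camera adjusted p = 7.1e-06; adjusted p = 0.364 with an estimated correlation). The dissociation and early response list was raised beside them, with 19 of 20 genes higher, 0 past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.000609; adjusted p = 0.591 with an estimated correlation). By edgeR, 0 genes passed in all cells (679 at an unadjusted p under 0.05, 19 by DESeq2), 0 in fibroblast-like cells (216 and 0) and 0 in vascular endothelial-like cells (261 and 0). Of 30 lists that passed over the classes, 0 held with an estimated correlation. With the pairs as a block, run at the preset correlation alone, 12 of the 30 passed in the same direction and 5 had too few measured genes. A further 5 lists passed in that fit alone.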

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

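All tests in this part on control libraries deposited with and without empty barcodes, all counts of other splits of the libraries, and the count of genes measured in no cluster, were chosen after the result was seen. The tests of the cluster mix, of RNA from other cells and of single libraries were written before.

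Single libraries stood far from the others of their group in 14 of 57 groups of 4 to 10 libraries, where chance gives about 1 in 20 for normally distributed values. Shares and CPM are bounded at 0 and skewed, and the rate for such values was not determined. In nonlesional skin, replicate 17 had the highest share of fibroblast-like cells, 10.2% (others up to 3.94%), and of hair shaft and inner root sheath-like cells, 14.7% (others up to 0.391%). Replicate 14 had 0.927% lymphatic endothelial-like cells (others up to 0.381%), replicate 18 had 5.03% melanocyte-like cells (others up to 1.70%) and replicate 13 had 67.5% vascular endothelial-like cells (others up to 34.0%). The median mitochondrial share was 12.6% in replicate 15 and at most 4.59% in the others. In keratinocyte-like cells of replicate 16 SERPINB2 stood at 187 CPM (others up to 41.7), and over all cells IFNG stood at 0.725 CPM in replicate 14 and 0 in the others.

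Among T and NK-like cells of controls, replicate 7 had the highest share of CD8 T-like cells, 20.8% (others up to 9.68%), with GZMK at 221 CPM (others up to 62.5) and PRF1 at 310 CPM (others up to 93.1). FKBP11 reached 664 CPM in control replicate 10 (others up to 229) and CXCL13 reached 1.1e+03 CPM in lesional replicate 29 (others up to 231). IL17A stood at 1.15e+03 CPM in control replicate 11 and between 20.4 and 323 in the other 5 controls. Between lesional and control T and NK-like cells 3 genes changed, and 5 of 100 splits of the libraries, the real one included, gave as many; the highest other split gave 12, so chance is not excluded for this count. The unnamed clusters 56 and 58, whose cells entered the sums and totals of all cells but no named class, held no control cell: cluster 56 (93 cells, led by H3C3 and TOP2A) and cluster 58 (116 cells, led by CD1A and HLA-DQB2, with all cells in lesional replicate 25).

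MHC class I genes were higher in lesional than control keratinocyte-like cells, with a median log2 fold change of 0.69. The mix of the 4 keratinocyte clusters tested is argued against as the whole cause. The median was at least 0.5 of the class value within 3 of 4 (0.56, 0.83 and 1.02 in clusters 11, 19 and 27). It was 0.15 in cluster 20 (camera unadjusted p = 0.14), which averaged 7.44% of control and 16.8% of lesional keratinocyte-like cells. Other clusters had too few libraries with enough cells to be tested. Among these, cluster 3 averaged 10.5% of control and 1.34% of lesional keratinocyte-like cells. A shift in the weight of the clusters not tested stays open as a cause. RNA of T and NK cells would need 9.97% of keratinocyte UMIs to give the rise of B2M, and 10 of their abundant genes rose by a median of 0.00489 of the amount needed; for vascular endothelial RNA (15.9% needed) the ratio was -0.0171. The form in which controls were deposited is argued against as well. The list's median was 0.727 against the controls deposited with called cells alone, as the lesional libraries were (12 of 12 genes higher, camera adjusted p = 9.86e-06), and 0.731 against the others, and both sets of controls differed by 0.0299. Disease of the lesional skin, as the design names it, stays a candidate explanation, and tissue handling (dissociation genes were raised in the same cells) stays open.

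Of the 206 genes that were lower in lesional keratinocyte-like cells, 134, 113, 92 and 186 were measured within clusters 11, 19, 20 and 27. Their medians there were -0.477, -0.724, -0.156 and -0.855, against -0.938, -0.845, -0.792 and -1.38 for the same genes in the class, so at least 0.5 was kept in 3 of 4 clusters. This argues against the mix of these 4 clusters as the whole cause. However, the genes had been called in these same libraries, so lower medians within clusters were partly built in. Clusters 3, 40 and 41, among others, had too few libraries with enough cells to be tested. Pooled over libraries, they held 613, 1299 and 1535 control cells and 59, 40 and 19 lesional cells. A single library gave 91.1% of cluster 40 and 92.1% of cluster 41. Per library, cluster 3 averaged 10.5 ± 7.49% of control and 1.34 ± 2.37% of lesional keratinocyte-like cells. Cluster 40 averaged 3.08 ± 6.90% and 0.602 ± 1.23%, and cluster 41 averaged 4.465 ± 8.57% and 0.316 ± 0.671%. A shift in the weight of clusters 3, 40 and 41 stays open as a cause. The mix also stays open for 12 genes measured in none of the clusters tested, which had fallen further (median -2.24 in the class). RNA from other cells was not tested for the 206 genes. Single libraries carried weight: the count of genes that fell was 100 without control replicate 7, 109 without 10 and 122 without 11, against 206. It was 131, 104, 137 and 132 without lesional replicates 20, 25, 26 and 30, so several libraries, not 1, carry the count. Against the 6 controls deposited with all barcodes alone, the median was -0.972 and 196 of 196 measured genes were lower, against -1.45 with all controls, but the genes had been called with these controls and 0 genes passed against them alone. These genes also lay lower in the controls with all barcodes than in the other controls (median -0.58), so part of their change could come from how the control libraries differ, and this cannot be told apart from disease for that part.

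For the 290 genes of keratinocyte-like cells between lesional and control skin, 1 of 100 splits, the real one, gave as many, and the highest other gave 1. This argues against chance as far as 100 splits can resolve, and does not exclude it. The splits did not keep the form of deposit of the controls. The count was 0 with only the controls deposited with all barcodes and 609 without them, and the splits cannot bear on that. In the comparisons of all cells, fibroblast-like and vascular endothelial-like cells, and the other comparisons of keratinocyte-like cells, the real count was 0. Any split gives at least as many, so these counts of splits cannot bear on chance. All cells had 60 splits in each comparison (highest other 1, 3 and 4 for lesional against control, nonlesional against control and lesional against nonlesional). Fibroblast-like cells (13, 5 and 48 in that order) and vascular endothelial-like cells (1, 160 and 4) had 100 splits each. In keratinocyte-like cells the highest other was 23 for nonlesional against control and 112 for lesional against nonlesional. A few splits gave many genes, but between 1 and 18 splits gave any gene, and the median was 0 in each comparison. Structure of the samples other than their groups was seen in the form of deposit of the controls (405 of 11922 genes in vascular endothelial-like and 0 of 13650 in keratinocyte-like cells). It was also seen in the pairs (r over 0.1 in 6 of 6 for keratinocyte-like cells). Whether the splits with many genes follow either was not tested.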

How the results depend on the processing

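Removing the highest doublet scores, keeping only the controls deposited with all barcodes, taking shares of named cells and leaving out single libraries (for shares and in keratinocyte-like and T and NK-like cells) were chosen after seeing the data. Among values of named genes that passed, 187 stayed past the threshold under the alternatives and 42 did not, 26 of these with only the controls deposited with all barcodes. For all of the following changes the cause was not tested, except that settings with fewer libraries or cells hold fewer counts. With edgeR on cell counts, 1 class differed between lesional and control skin, 0 between nonlesional and control skin and 1 between lesional and nonlesional skin, and 1 T and NK-like subclass differed (also 1 at 1000 UMIs). The class that differed in nonlesional skin was lost (0) at 1000 UMIs, at Leiden resolution 2, and without or with only the controls with all barcodes; leaving out each library in turn gave 0 to 1.
For lesional against control skin, all cells gave 6 genes at 1000 UMIs, 3 at 10% mitochondrial UMIs, 2 without doublet removal, 241 without the controls with all barcodes and 161 with DESeq2. Keratinocyte-like cells gave 609 without those controls, 0 with only them and 568 with DESeq2; 226 of the 609 were among the 290. Leaving out each library in turn gave 133 to 383: 133, 192, 148 and 167 without control replicates 7, 8, 10 and 11, and 187, 144 and 182 without lesional replicates 21, 25 and 26. Fibroblast-like cells gave 14 without the low-count filter, 1 at 10% mitochondrial UMIs, 1 without the controls with all barcodes and 3 with DESeq2, and vascular endothelial-like cells 1 with only those controls. T and NK-like cells gave 97 without the low-count filter, 0 at 1000 UMIs, 6 without the highest doublet scores, 5 without those controls and 0 to 9 when each library was left out in turn. For nonlesional against control skin, all cells gave 1 without those controls, fibroblast-like cells 2 without the low-count filter and vascular endothelial-like cells 2 with only those controls.
For lesional against nonlesional skin, all cells gave 19 with DESeq2. Keratinocyte-like cells gave 1 without the low-count filter, 1 at 1000 UMIs, 15 at 10% mitochondrial UMIs, 1 without the highest doublet scores, 13 with DESeq2 and 4 with the pairs as a block. Fibroblast-like cells gave 1 without the low-count filter. With an estimated correlation 3, 0 and 0 gene lists passed in the 3 comparisons. With the pairs as a block, at the preset correlation, 17 passed between lesional and nonlesional skin (12 of them among the 30). The pairs changed no other count of genes or classes. For classes this could hardly have come out otherwise, because a test over 6 pairs gives too coarse a p for adjustment over 12 classes. The difference in CD4 T-like share turned to 0.76 points without the controls with all barcodes, and GZMB in T and NK-like cells turned to a log2 fold change of 0.0936 without the low-count filter; neither had passed. Of the other values that had not passed, 131 of genes and 52 of shares stayed so, and 14 and 1 passed. For the share that passed, 5 values stayed past the threshold and 4 did not, nor did edgeR on cell counts (adjusted p = 0.216). Myeloid-like cells, and T and NK-like cells outside lesional against control skin, had too few libraries to give a value, and the depth of the smallest library, 160 cells, limits shares of rare classes.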

Other observations

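All tests in this part were run on the planned gene lists and classes, and the comparison of control libraries by their form of deposit was chosen after the data were seen.

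Between lesional and nonlesional skin over all cells, genes of sebaceous lipid synthesis were higher for 14 of 14 genes (median log2 fold change 0.86, 0 past the threshold by edgeR and 0 adjusted over the list alone, camera adjusted p = 0.00184; adjusted p = 0.413 with an estimated correlation). With the pairs as a block this list pointed down (camera adjusted p = 0.786), and sebocyte-like cells themselves made up 2.63% of lesional and 0.933% of nonlesional cells (exact permutation p = 0.174, adjusted p = 0.416). Higher as well were 10 of 11 pigmentation genes (median 0.35, 0 and 0, camera adjusted p = 0.00887; adjusted p = 0.476 with an estimated correlation). Epidermal differentiation genes were lower for 11 of 12 (median -0.74, 0 and 0, camera adjusted p = 0.000207; adjusted p = 0.411 with an estimated correlation). Both of these passed in the same direction with the pairs as a block (camera adjusted p = 9.78e-26 and 0.0446). That fit was run at the preset correlation of 0.01 alone, which treats the genes as nearly independent. Its p-values were not tried with an estimated correlation, with which both calls were lost in the main fit. In fibroblast-like cells of nonlesional against control skin, the extracellular matrix list was raised with 15 of 18 genes higher (median 0.34, 0 and 0, camera adjusted p = 0.00587; adjusted p = 0.859 with an estimated correlation). The heat shock list, a sign of tissue handling, was lowered beside it with 13 of 13 genes lower (median -0.451, 0 and 0). Its camera adjusted p was 0.0111, or 0.859 with an estimated correlation. Over all cells of this comparison the extracellular matrix list was lowered instead, with 18 of 18 genes lower (median -0.545, 0 and 0). There the camera adjusted p was 5.51e-06, or 0.643 with an estimated correlation. Sums over all cells also follow the shares of the classes. Only 5 nonlesional libraries entered for fibroblast-like cells.

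The endothelial activation list was lowered in vascular endothelial-like cells of lesional against control skin, with 10 of 11 genes lower (median -0.39, 0 past the threshold by edgeR and 0 adjusted over the list alone, camera adjusted p = 0.000581; adjusted p = 0.481 with an estimated correlation). The keratinocyte activation list, whose genes belong to another cell type, was lowered in the same cells with 6 of 7 genes lower (median -1.57, camera adjusted p = 0.000581; adjusted p = 0.481 with an estimated correlation). The mitochondrially encoded list, a sign of RNA quality, was raised beside them with 12 of 12 genes higher (camera adjusted p = 0.00194, or 0.757 with an estimated correlation). Whether the fall of the keratinocyte activation list came from keratinocyte RNA in these droplets was not tested.

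Control libraries deposited with all barcodes differed from the other controls by 405 of 11922 genes in vascular endothelial-like cells (176 higher, 229 lower, edgeR), against 4 of 18772 over all cells and 0 of 13650 in keratinocyte-like cells (1313 at an unadjusted p under 0.05).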
